A study of Mus musculus with 4 samples.

How the data were processed

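Total RNA of 4 mouse lymphoma cultures was labelled with biotin and hybridised to Illumina bead arrays, per the labels' protocols. The submitters' processing notes name GenomeStudio, and its version is not given in the sources used here. Per the file headers, the deposited table without normalization holds, for each of 45281 probes and each array, a mean bead intensity on a linear scale. It also holds a detection p-value per probe and array, deposited without adjustment, which ranks the probe against negative control beads. The detection columns carry slide positions in place of sample names. Each was linked to a signal column by its values: its p-value never rose as its own array's signal rose, in 0 of the ordered probes, and rose at no fewer than 16710 probes when ordered by another array's signal. The header positions also showed that both arrays without DOX came from 1 slide and both arrays with DOX from the other. The authors' processed values, a deposited table of intensity with 1 column per array, were compared with the other table. On each array they kept the order of the probes, with 0 rank breaks, and a linear relation (r = 1), so they are a rescaling per array, whose method is not given in the sources used here. Their medians were 146.9 and 143.2 on the arrays without DOX and 100.9 and 104.6 on those with DOX, control cells first. Their scale is linear, they are not centred, and they have no direction, being levels.

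The values reported here start from the table without normalization. The median raw signal was 138.7 and 159.5 on the arrays without DOX and 127.3 and 119.0 on those with DOX. Background was corrected with limma 3.58.1 in R 4.3.3 by the normal-exponential method, with the negative control level inferred from the detection p-values. An offset of 16 was added, log2 was taken and the 4 arrays were quantile normalized together. Quantile normalization gives each array the same distribution, so ratios are relative to the other genes, and a loss of RNA common to all genes with MYC off would not be seen. Gene names came from the platform annotation, in which 34885 probes had 1 gene, 18 had several and 10378 were unnamed. Of the named probes 34807 were matched to current mouse symbols by gene number, and 78 kept the annotation's symbol. Each gene was represented by its brightest detected probe, which gave 19057 genes on the array and 8674 with a detection p of at most 0.01 on at least 1 array. Of the genes analysed, 3502 had several detected probes. Where the brightest was past 2-fold, the next probe went the same way for 95.5% of genes in the DOX effect of the control cells and for 76.2% in the miR-17-92 effect with MYC on. The spread per probe was log2 0.33 and 0.19 over all these genes. It is the robust SD of the gap between both probes divided by the square root of 2, so the gap itself spreads more widely. No genome coordinates were used here.

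Samples were grouped by their labels, with 1 array per group. The comparisons were DOX against no DOX in each line, miR-17-92 against control cells without and with DOX, and the difference of both DOX effects. A 2-fold ratio was the threshold of size. A gene undetected on its dim side was given as a lower bound, the ratio of the bright array to the higher of the dim probe's own signal and the lowest signal among detected probes of the dim array. Counts past 2-fold and list medians use the measured ratios of such genes, and the alternative with detection on all 4 arrays leaves them out. No fold or ratio was given for a single gene that neither array of a comparison detected, no difference of the DOX effects for the named extremes undetected on any array, and no fold where the bound was under 1. The named genes are the 12 highest and 12 lowest in each DOX comparison and the 8 highest and 8 lowest in each other comparison, with clone and predicted names passed over. The 5 targets named by the study, the MYC network genes and Mir17hg were named whatever their values, and up to 4 members with the largest absolute log2 ratio were examples of each of 36 gene lists. Other members are named where they complete a count or carry a contrast between comparisons. These rules, the lists, the normalization and the alternatives were fixed before the data were examined. Members of the lists are textbook or reported genes, and the list of 5 targets comes from knowledge of the study.

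With 1 array per group no test across replicates was run. The median log2 ratio of each of the 31 lists with at least 3 analysed genes was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 10 bins. A percentile describes these arrays only. The size of the whole response was compared by the SD of log2 ratios and by the orthogonal slope, which treats both lines alike. The procedure was tested on simulated data for the DOX effect in control cells, with 8975 genes in the step. Of 100 genes with a simulated 4-fold change, a log2 of 2, 99% passed 2-fold, and of 100 with a 2-fold change 44% did, all in the right direction. Of the genes with no simulated effect 0% passed. The simulated arrays were made from 1 real array with small random noise, and 8775 of the 8975 genes were left unchanged. The real DOX effects moved a far larger share of genes, so 0% is not an error rate of the real arrays. A slope of 0.5 was recovered as 0.497, and 5.5% of 200 lists with no effect lay outside percentiles 2.5 to 97.5. Those lists were random genes with independent noise. Members of the real lists can move together, so this share does not carry over to them. Figures and tables used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Alternatives were no background correction, median scaling, an offset of 50, the authors' processed values, a detection p of 0.05, detection on all 4 arrays, no detection filter, the mean of a gene's probes, unmatched random lists and the interquartile range in place of the SD.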

Results

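Gene expression was measured on 4 Illumina mouse bead arrays of CL4188 cells, a line of conditional MYC lymphoma from FVB/N mice in which doxycycline (DOX) shuts off MYC. The cells carried either the empty retroviral vector MSCV (control cells) or MSCV with the microRNA cluster miR-17-92 (miR-17-92 cells). Each line was profiled without DOX and after DOX at 20 ng/ml for 48 hours. The 4 groups held 1 array each, so no difference below has a replicate check, and no p-value or SE is given. Of 45281 probes per array, 13251 were detected in the control cells without DOX and 13656 in the miR-17-92 cells without DOX. With DOX these numbers were 14864 and 14658. After the choice of 1 probe per gene, 8674 genes were detected on at least 1 array and analysed. The number of arrays limits the precision of every value below.

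The mouse Myc probe matched the labels. Myc signal was at least 6.28-fold lower with DOX in the control cells and at least 5.80-fold lower in the miR-17-92 cells, and it was not detected on either DOX array. Without DOX it differed by log2 -0.07 between the lines. The probe reads mouse Myc, and the labels do not say which species' MYC the transgene encodes. The probe for Mir17hg, the primary transcript that hosts the endogenous miR-17-92 cluster, was 12.4-fold lower with DOX in the control cells and 7.71-fold lower in the miR-17-92 cells. It differed by log2 -0.13 between the lines without DOX and by 0.55 with DOX. Mature microRNAs are not read by these arrays, so the level of miR-17-92 delivered by the vector was not measured. Among MYC network partners in the control cells, Mxd4 was 7.14-fold higher with DOX and Mxd1 at least 2.39-fold higher, both encoding repressors that compete with MYC for MAX. The Mxd3 probe was 2.60-fold higher and Mlx 2.04-fold higher, while Max differed by log2 0.06 and Mxi1 by 0.22. Mga was detected with DOX alone, too close to the detection floor for a fold. Mycn, Mycl and Mnt were not detected on any array.

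**Figure D1:**
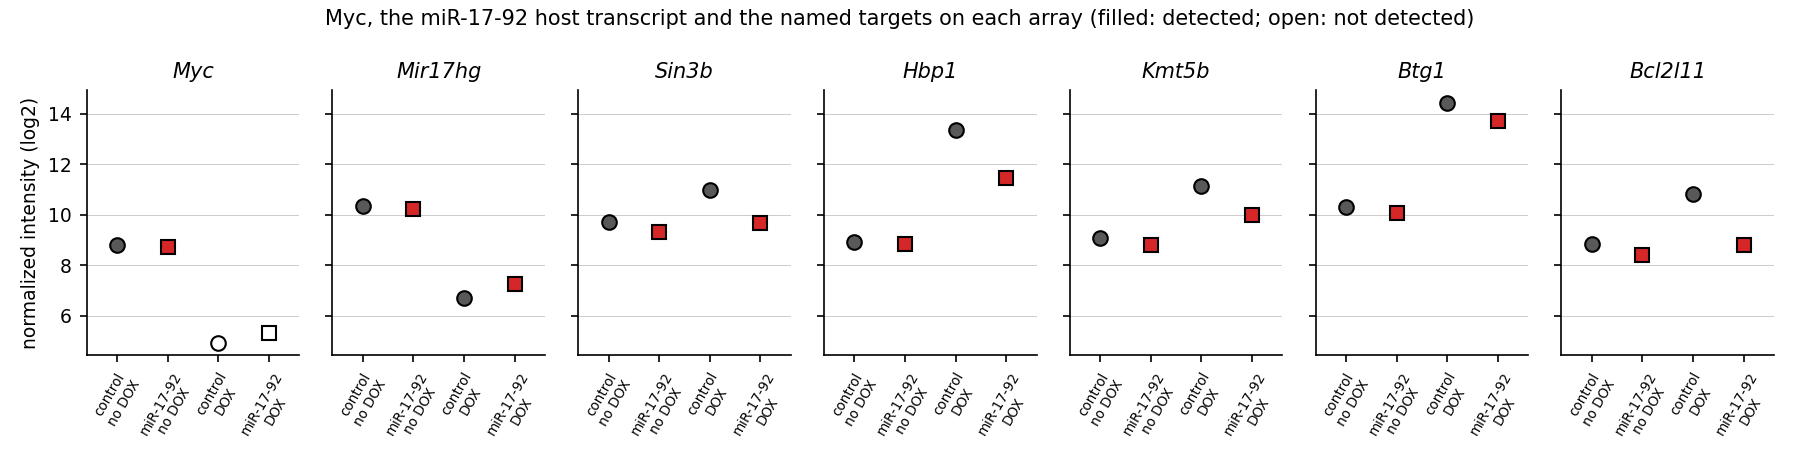
Normalized intensity (log2) of Myc, Mir17hg and the 5 targets named by the study on each of the 4 arrays. Circles are control cells, squares miR-17-92 cells, filled symbols detected and open symbols not detected; Hbp1 was 21.6-fold higher with DOX in control cells and 6.12-fold higher in miR-17-92 cells.

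The first comparison, DOX against no DOX in the control cells, asked what switching MYC off does to the lymphoma cells. Srm, which encodes spermidine synthase, was 143-fold lower with DOX, Shmt1, a serine hydroxymethyltransferase, 103-fold lower, and Bcat1, the cytosolic branched-chain aminotransferase, 55.5-fold lower. Gsto1 was 68.0-fold lower, Rangrf 42.3-fold, Mt1, a metallothionein, 37.8-fold, Efhd1 34.9-fold and Polr1b, a subunit of RNA polymerase I, 31.3-fold. Car12 was at least 30.7-fold lower, Fkbp11 at least 34.2-fold, Fjx1 at least 18.6-fold and Pdia5 at least 12.9-fold. Cd6, a T-cell surface receptor, was 118-fold higher, Cd52, a lymphocyte surface glycoprotein, 59.6-fold, Txnip, which encodes a brake on glucose uptake, 51.6-fold, and Tctex1d1 34.7-fold. Hsd11b1, the enzyme that regenerates active glucocorticoid, was at least 146-fold higher. Abi3 was at least 32.7-fold higher, Prr33 22.1-fold, Eci3 17.0-fold, Myo1f 16.1-fold, Clec2d 14.3-fold, Socs3, a feedback inhibitor of cytokine signalling, 13.3-fold and Cd69, an early activation marker, 11.4-fold, each as a lower bound.

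By fixed gene list, all 26 analysed ribosome biogenesis genes were at least 2-fold lower with DOX in the control cells, with a median log2 ratio of -2.63. Polr1b (-4.97), Rrp12 (-4.60), Rrp1b (-4.09) and Polr1a (-3.70) were the lowest of them. Of 26 genes reported as activated by MYC, 23 were 2-fold lower and 3 lay within 2-fold (median -2.19), among them Srm and Apex1 (-3.75), and Ccnd2, the gene of cyclin D2, at least 12.2-fold lower. Of 19 nucleotide synthesis genes 14 were 2-fold lower (median -1.60), including Cad (-4.14), which starts pyrimidine synthesis, Gart (-3.64), Dhodh (-3.28) and Ctps (-2.82). Of 18 genes of mitochondrial translation 15 were 2-fold lower (median -1.66), for example Mrps18b (-2.42) and Gfm1 (-2.07). DNA replication genes followed, with 22 of 29 2-fold lower and 7 within 2-fold (median -1.45), among them Mcm6 (-3.02), Mcm3 (-2.24) and Mcm10 (-2.17) of the replicative helicase machinery and Gins2 (-2.71). Mitosis genes stood apart from these, with 22 of 24 within 2-fold (median -0.11), and Nuf2 (-1.63) and Aurkb (-1.03) past 2-fold lower. The medians of the first 5 of these lists lay at percentile 0 of 10000 random lists matched on expression, and that of the mitosis list at percentile 35.5.

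Quiescence genes were higher with DOX in the control cells, 20 of 22 by at least 2-fold (median 1.86, percentile 100). They included Txnip (5.69), Hbp1 (4.43), a transcriptional repressor that restrains the cell cycle, Pik3ip1 (4.16), an inhibitor of PI3 kinase, and Btg1 (4.13), an antiproliferative gene. Below 0 were Cdkn2a (-0.84), which encodes cell-cycle inhibitors, and Cdkn1a, which was not detected in the control cells. Of 17 T-cell genes 15 were 2-fold higher and 2 within 2-fold (median 1.73, percentile 100), with Cd27 (2.99), Cd247 (2.73), Cd4 (2.53) and Cd2, which was at least 7.89-fold higher. Mature T-cell genes were 2-fold higher in 6 of 8 cases (median 2.14), with Itgb7 at least 12.5-fold higher. Of 11 immature thymocyte genes on the array 4 were analysed, all above 2-fold by measured ratio (median 1.69). Rag1 stood at 2.37 and Rag2 was at least 5.54-fold higher, while Notch1 was too close to the detection floor for a fold. Of 13 pro-apoptotic genes 5 were 2-fold higher, 1 lower and 7 within 2-fold (median 0.85, percentile 97.7). Fas (3.71), a death receptor, Bbc3 (2.34), the gene of PUMA, and Bcl2l11 (1.98), the gene of BIM, were higher, and Bid (-2.16) was lower. Anti-apoptotic genes were higher as well, 6 of 8 by 2-fold (median 1.65, percentile 99.9), with Cflar at 2.32 and Mcl1 at 1.98. Of 53 markers of B, myeloid, natural killer, erythroid and stromal cells on the array, 2 were detected on each array without DOX and 4 on each with DOX. The added ones were Vpreb1, at least 3.24-fold higher in the control cells, and Itgam, at least 1.75-fold higher.

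In total 1722 genes were at least 2-fold higher and 1565 at least 2-fold lower with DOX in the control cells, 37.9% of those analysed, of which 52.4% were higher. With the authors' processed values the split was 946 higher and 1414 lower, or 40.1% higher. Both arrays without DOX came from 1 slide and both with DOX from another, so DOX and slide cannot be told apart in this comparison or in the next.

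The same comparison in the miR-17-92 cells asked how the cells respond to MYC loss when the cluster is expressed from the vector. Many of the same genes stood at the extremes. Srm was 73.1-fold lower, Bcat1 46.3-fold, Rangrf 40.5-fold, Gsto1 38.9-fold, Ydjc 28.6-fold, Fkbp11 28.5-fold, Mt1 24.5-fold and Efhd1 24.1-fold. Lower bounds were 39.6-fold for Car12, 28.6-fold for Mcrip2, 13.5-fold for Pdia5 and 11.6-fold for Pcsk4. Cd6 was 99.6-fold higher. Tctex1d1 was higher by at least 58.5-fold, Hsd11b1 by at least 55.0-fold, Tespa1, a component of T-cell receptor signalling, by at least 36.1-fold, Spon2 by at least 27.6-fold, Cd52 by at least 23.8-fold and Abi3 by at least 12.4-fold. Lower bounds were 11.5-fold for Myo1f, 10.9-fold for Sema7a, 10.7-fold for Slamf1, 10.5-fold for Itgb7 and 8.05-fold for Cd69.

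Ribosome biogenesis genes were 2-fold lower in 25 of 26 cases in the miR-17-92 cells (median -2.45), with Polr1b at -4.52 and Rrp1b at -3.73. Of 26 genes reported as activated by MYC, 19 were 2-fold lower (median -1.29), and 12 of 19 nucleotide synthesis genes (median -1.26) and 11 of 18 of mitochondrial translation (median -1.31) were too. All 4 lists lay at percentile 0. DNA replication genes behaved otherwise. Of 29, 1 was 2-fold higher, none was 2-fold lower and 28 were within 2-fold (median 0.01, percentile 35.6), from Orc1 (-0.92) to Gins3 (1.07). The sign of this median was not stable, since it was -0.22 with median scaling, -0.16 with the authors' processed values and -0.05 with the mean of a gene's probes. Mitosis genes were above 0 in 23 of 24 cases and 2-fold higher in 7 (median 0.60, percentile 99.8), led by Cenpf (1.73) and Nusap1 (1.62). Of 13 glycolysis genes 8 were 2-fold higher and none lower (median 1.18, percentile 100), with Hk1 (1.63), Slc2a1 (1.45), which encodes the glucose transporter GLUT1, and Pkm (1.31). Hypoxia genes were 2-fold higher in 7 of 11 cases (median 1.13, percentile 100), for example Ddit4 (3.32) and Ankrd37 (1.99).

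Quiescence genes were 2-fold higher in 14 of 22 cases in the miR-17-92 cells (median 1.67) and T-cell genes in 11 of 17 (median 1.25), both at percentile 100. Txnip (4.40), Ccng2 (3.82) and Btg1 (3.63) led the quiescence list, and Cd27 (2.83) and Bcl11b (2.10) were among the T-cell genes. Of 13 pro-apoptotic genes 2 were 2-fold higher, Fas (3.16) and Bik (1.60), 1 was lower, Bid (-1.86), and 10 were within 2-fold (median 0.38, percentile 84.2). Bcl2l11 stood at 0.38. Of 8 anti-apoptotic genes 4 were 2-fold higher (percentile 99.2), with Cflar at 2.45. Vpreb1, the B-cell marker, was too near the floor for a fold, and Itgam was at least 1.13-fold higher. Of the network genes, Mxd4 was 3.71-fold and Mlx 1.32-fold higher, Mxd3 at least 3.76-fold higher, Max 1.46-fold and Mxi1 1.11-fold lower, and Mxd1 and Mga gave no fold. In total 1281 genes were at least 2-fold higher and 1108 at least 2-fold lower, 27.5% of those analysed. The higher share was 53.6%. With the authors' processed values the counts were 661 higher and 942 lower (41.2% higher), and without background correction 796 and 772.

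**Figure D2:**
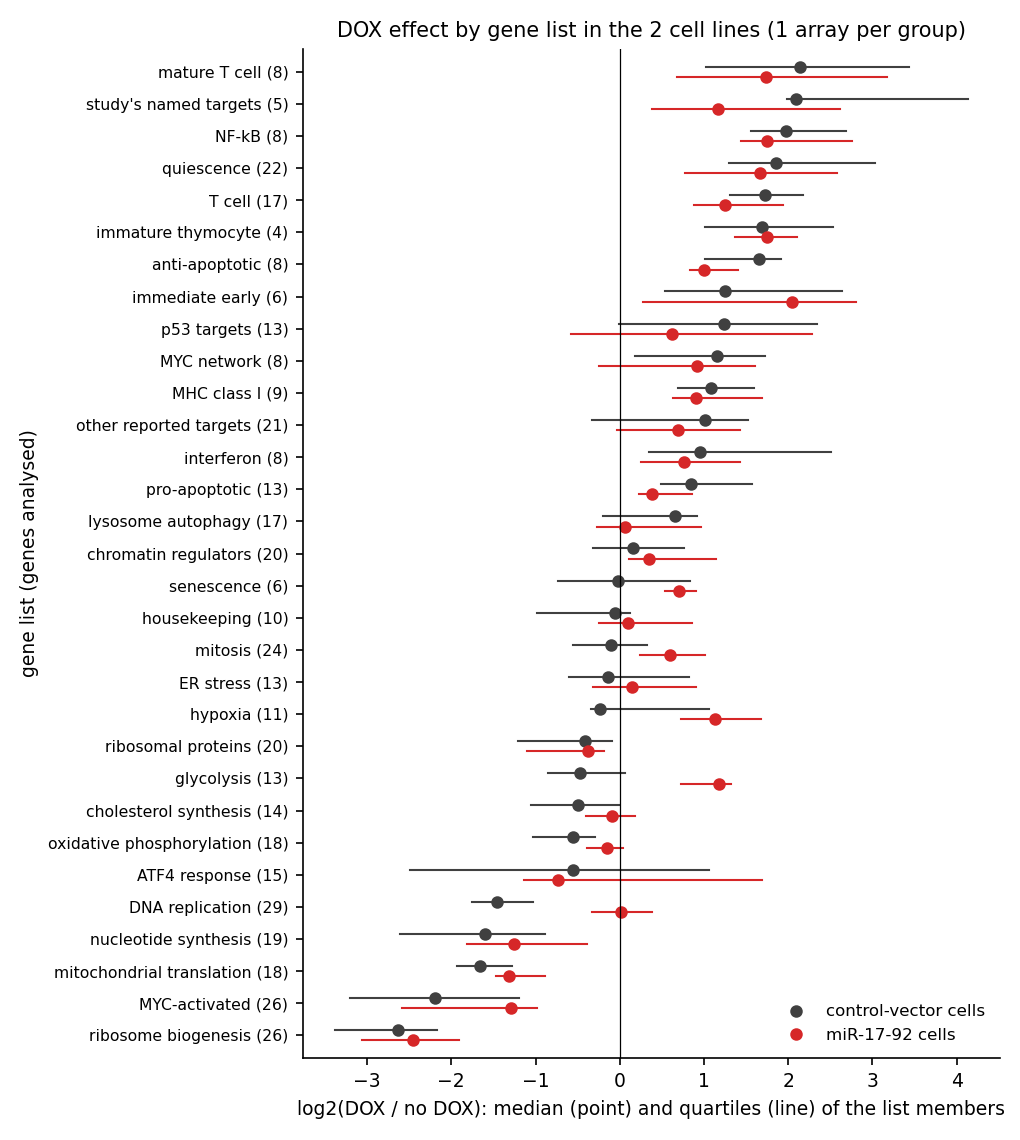
Median log2 ratio of DOX over no DOX for each gene list with at least 3 analysed genes, in control cells (grey) and miR-17-92 cells (red), with lines for the quartiles of the members. The DNA replication median was -1.45 in control cells and 0.01 in miR-17-92 cells, and the glycolysis median -0.48 and 1.18.

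The difference of the DOX effects (miR-17-92 cells minus control cells) asked which parts of the response to MYC loss differ when the cluster is expressed. DNA replication genes gave the clearest group. All 29 lay above 0 and 26 were at least 2-fold above it (median 1.51, percentile 100), led by Gins2 (2.82), Mcm6 (2.56), Pold1 (2.05) and Lig1 (1.85). All 13 glycolysis genes lay above 0, 8 of them by 2-fold (median 1.21, percentile 100), with Aldoa (2.03), Pfkl (2.00), Pgam1 (1.95) and Tpi1 (1.80). Mitosis genes were above 0 in all 24 cases and by 2-fold in 7 (median 0.85), and hypoxia genes in 10 of 11, with 4 above 2-fold and Ndrg1, undetected in the control cells without DOX, below 0 (median 0.96). In contrast, 26 of 26 ribosome biogenesis genes were within 2-fold (median 0.38, percentile 99.7). Quiescence genes were below 0 in 17 of 22 cases (median -0.47, percentile 0.08), and pro-apoptotic genes in 11 of 13 (median -0.47, percentile 1.26), with Bbc3 (-2.09) and Bcl2l11 (-1.60) the lowest. After the control effects were scaled by the orthogonal slope over all genes, a test chosen after the results were seen, quiescence genes had a median of 0.09 left (percentile 75.3), pro-apoptotic genes -0.11 (percentile 27.3) and MYC-activated genes 0.09 (percentile 69.3), while DNA replication (1.21) and glycolysis genes (1.14) stayed at percentile 100. Anti-apoptotic genes had -0.28 left (percentile 9.45). A median near 0 does not speak for each member. Other lists also kept a residual after the scaling. Mitosis (0.79) and ATF4 response genes (0.65) lay at percentile 100, and hypoxia genes (0.91) at 99.99. Cholesterol synthesis (0.45), nucleotide synthesis (0.31) and senescence genes (0.51) lay at percentiles 99.6, 98.9 and 98.15. Below 0 were the study's targets (-0.70, percentile 0.16), p53 targets (-0.39, 1.04), T-cell (-0.20, 1.1) and ribosomal protein genes (-0.11, 2.42).

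Among single genes at the upper extreme of the difference, Gins2, Dscc1 (2.78), Chek1 (2.65), which encodes the S-phase checkpoint kinase CHK1, and Ung (2.56), the uracil DNA glycosylase, were detected on all 4 arrays, as were Shmt1 (2.69) and Prelid2 (2.62). Crhbp and Bhlhe40 also stood there but were not detected on every array. On the other side Grasp (-3.03) was detected on all 4 arrays. Vsir, which encodes the checkpoint receptor VISTA, Prr33, Calcrl, Socs3, Ifit1bl1, Clec2d and Brd1 were undetected on at least 1 array, so their place there rests partly on the background and no value is given.

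Across genes the DOX effects of the lines were close, with Pearson's r of 0.86 and Spearman's rho of 0.82. These were computed across genes, which are not independent replicates. Both lines were 2-fold higher for 980 genes and 2-fold lower for 893, where independent lists would share 254.3 and 199.9. Both DOX effects contrast the same slides, so a shared slide effect cannot be told apart from DOX in this agreement. The response of the miR-17-92 cells was smaller, with an SD of log2 ratios of 1.08 against 1.28 in the control cells, a ratio of 0.841, and an orthogonal slope of 0.818. Of 3287 genes picked by a 2-fold effect in the control cells, 95.6% went the same way in the miR-17-92 cells and 82.5% had a smaller effect there (median ratio 70.7%). Of 2389 genes picked in the miR-17-92 cells, 45.6% had a smaller effect in the control cells (median ratio 104%), and picking by either line shrinks the other through noise alone. The difference was at least 2-fold above 0 for 616 genes and below it for 418, a share above 0 of 59.6%. These counts depended on the processing, with 318 and 126 (71.6% above 0) with the authors' processed values and 295 and 168 without background correction. A slide effect common to both lines cancels in this difference, but it rests on 4 arrays with no error estimate.

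**Figure D3:**
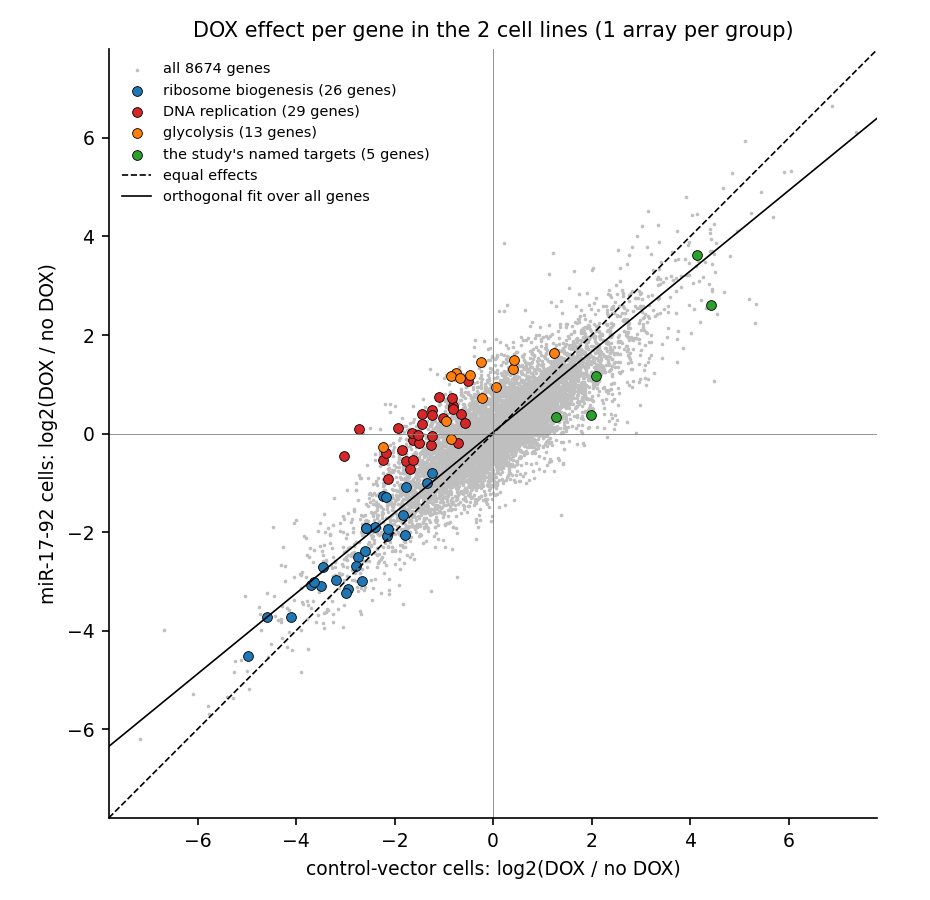
Log2 ratio of DOX over no DOX in miR-17-92 cells (vertical) against control cells (horizontal) for all 8674 genes, with 4 gene lists in colour, the line of equal effects (dashed) and the orthogonal fit with slope 0.818 (solid). Ribosome biogenesis genes lie near both lines, and DNA replication genes, with a median difference of 1.51, lie above it.

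With MYC on, the comparison of miR-17-92 cells with control cells asked what the vector does while MYC is high. Few genes differed. The 5 targets that the study is known to name were all slightly lower in the miR-17-92 cells and all within 2-fold (median -0.25, percentile 1.89, or 3.90 of lists not matched on expression), Bcl2l11 by log2 -0.43, the co-repressor gene Sin3b by -0.37, the histone methyltransferase gene Kmt5b by -0.25, Btg1 by -0.24 and Hbp1 by -0.07. The sign for Hbp1 turned to 0.04 with the mean of its probes. The study may have chosen this list on these samples, so its count is not independent evidence of a direction. Of 21 targets of the cluster reported in other work, 12 were below 0 and 20 within 2-fold (median -0.11, percentile 4.34), with Ccnd1 (1.26) above 2-fold. Ribosome biogenesis, MYC-activated, DNA replication, mitosis and glycolysis genes all lay within 2-fold, with medians of 0.01, 0.05, -0.13, -0.03 and 0.03. The DNA replication median, although small, lay at percentile 0.04.

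The genes that differed most with MYC on were dim. Higher in the miR-17-92 cells were Sertad4 (at least 5.05-fold), Tcea3 (4.73-fold), Nipa1 (3.13-fold), Sccpdh (3.12-fold), Smpd3 (2.14-fold), Bex4 (1.54-fold), Sp5 (1.15-fold) and Catsperz (1.07-fold), all as lower bounds because they were not detected in the control cells. Lower were Pkd1l2, by 3.38-fold and detected in both lines, and as lower bounds Tspoap1 (3.07-fold), Rab3d (2.32-fold), Slc29a2 (1.49-fold), Mtmr4 (1.47-fold), Arhgef26 (1.45-fold), Inpp5b (1.22-fold) and Erf (1.15-fold). Mxd3 was at least 1.29-fold lower. In total 102 genes were 2-fold higher and 90 lower, 2.21% of those analysed, and with detection on all 4 arrays required these were 11 and 16. Of the genes past 2-fold 53.1% were higher, against 66.7% of 6 higher and 3 lower with the authors' processed values. The spread per probe, taken from the gap between probes of 1 gene, was log2 0.19 in this comparison.

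With MYC off, the same comparison asked what expression of the cluster holds down or keeps up once MYC is gone. All 5 targets named by the study were lower in the miR-17-92 cells (median -1.30, percentile 0). Bcl2l11 was 4.10-fold lower, Hbp1 3.71-fold, Sin3b 2.46-fold, Kmt5b 2.26-fold and Btg1 1.67-fold. These are the brightest probes. All 14 detected probes of these genes were lower, from log2 -2.03 to -0.33 over 3 probes of Bcl2l11, -2.24 to -1.44 over 4 of Hbp1, -1.26 to -0.87 over 4 of Kmt5b and -1.24 to -0.74 over 2 of Btg1, and Sin3b rests on 1 probe. This count, too, is not independent evidence, as the study may have chosen the list on these samples. Of the 21 targets reported elsewhere, 14 were below 0, 1 of them by 2-fold, Txnip (-1.28), and 2 were 2-fold higher, E2f1 (1.30) and Cdkn1a, at least 3.85-fold and undetected in the control cells (median -0.30, percentile 2.52).

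DNA replication genes were 2-fold higher in the miR-17-92 cells with MYC off in 23 of 29 cases (median 1.42), for example Gins2 (2.38), Mcm6 (2.33) and Pold1 (1.84). Glycolysis genes were 2-fold higher in 9 of 13 (median 1.45), for example Pfkl (2.16), Tpi1 (1.94) and Aldoa (1.85), and mitosis genes in 6 of 24 (median 0.81), such as Nuf2 (1.83) and Aurkb (1.34). Of 26 MYC-activated genes 9 were 2-fold higher (median 0.66), with Odc1 (1.63), the first enzyme of polyamine synthesis, and Slc3a2 (1.44), although its median difference of the DOX effects was near 0 after the scaling given above. These 4 lists lay at percentile 100. Ribosome biogenesis genes were all within 2-fold (median 0.36, percentile 99.6). Quiescence genes were lower in 16 of 22 cases, 4 of them by 2-fold (median -0.55, percentile 0), with Hbp1, Pik3ip1 (-1.46) and Slfn2, which was not detected in the miR-17-92 cells, while Cdkn1a was higher by at least 3.85-fold. Of 13 pro-apoptotic genes 11 were below 0 (median -0.43, percentile 1.82), with Bbc3 (-1.96) next to Bcl2l11, and Bik (1.29) 2-fold higher. T-cell genes were below 0 in 15 of 17 cases and all within 2-fold (median -0.58, percentile 0.01). Vpreb1 (-1.91), the B-cell marker seen with DOX, and Itgam (-0.77) were lower as well.

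At the extremes with MYC off, Prelid2 was 7.47-fold, Shmt1 6.49-fold, Tcea3 6.45-fold and Gcat, an enzyme of threonine and glycine metabolism, 6.43-fold higher. Crhbp was higher by at least 6.82-fold, Sccpdh by at least 4.92-fold, Bhlhe40 by at least 3.26-fold and Adgrb3 by at least 2.75-fold. Prr33 was 9.25-fold lower, Marchf2 7.46-fold, Tec, a tyrosine kinase of lymphocytes, 6.16-fold, Grasp 5.89-fold and Rab3d 5.85-fold. Vsir was lower by at least 10.5-fold, Arhgef26 by at least 6.39-fold and Ifit1bl1 by at least 3.15-fold. Of the MYC network, Mxd1 was 2.73-fold and Mxd4 2.17-fold lower, Mlx 1.65-fold lower, Max differed by log2 -0.57, and Mxd3, Mxi1 and Mga differed by log2 0.16, -0.03 and -0.05. In total 552 genes were 2-fold higher and 419 lower, 11.2% of those analysed, and 56.8% of them were higher. With the authors' processed values these were 336 and 166 (66.9% higher), and without background correction 293 and 204. Both miR-17-92 comparisons lie within a slide, and across genes their log2 ratios had an r of 0.25 and a rho of 0.23.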

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

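The technical tests in this part were chosen after the results were seen. Differences between the lines listed here were picked because a median went opposite ways in the lines, and they were not tested against replicates, since each group has 1 array.

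DNA replication genes had a median DOX effect of log2 -1.45 in the control cells and 0.0117 in the miR-17-92 cells, while ribosome biogenesis genes were low in both, at -2.63 and -2.45. If the miR-17-92 cells had merely a uniformly weaker response, scaling the control effects by the slope over all genes would remove the gap, and a median of 1.21 was left, at percentile 100 of matched random lists. The normalization is argued against by the range of the gap over all settings, 1.31 to 1.51. A share of cells that kept MYC on would have to be 91.2% by the 22 replication genes past 2-fold, while the 100 genes lowest in the control cells allow 3.55% and 26 ribosome biogenesis genes 3.90%. What stays open is a difference between the single cultures, or, as a hypothesis, that miR-17-92 may keep the replication programme on after MYC loss.

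Glycolysis genes had medians of -0.48 in the control cells and 1.18 in the miR-17-92 cells. The gap stayed between 1.06 and 1.43 over all settings, which argues against the normalization. Compression of very bright probes would move equally bright genes alike, but random lists of that brightness had a median gap of 0.0420, and the glycolysis list lay at percentile 100 of them. Conditions of the single dish, such as density, oxygen or medium, cannot be told apart from the cluster, and 9 hypoxia genes outside the list had a gap of 0.957 as well. An effect of miR-17-92 on sugar metabolism may also account for the pattern and stays untested without a second dish.

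Hypoxia genes had medians of -0.24 in the control cells and 1.13 in the miR-17-92 cells. Mitosis genes had medians of -0.11 and 0.60. Of 13 senescence genes on the array 6 were analysed, with medians of -0.0165 and 0.71. The first of these was above 0 without background correction, with an offset of 50 and with each other detection filter. In the miR-17-92 cells 5 were above 0, with Tgfb1 at 1.23, Lmnb1 at 0.93 and Glb1 at 0.83, and Cdkn2a was at -0.62. The median pools members without regard to the direction each takes in senescence, so it gives no verdict on senescence. Past 2-fold in opposite directions by measured ratio were 1 gene higher in the control and lower in the miR-17-92 cells, Grasp (1.38 and -1.65), and 3 genes lower in the control and higher in the miR-17-92 cells, Bhlhe40 (1.31 in the miR-17-92 cells), Epb41l3 and Gria2. Epb41l3 and Gria2 were named after their values were seen. Grasp was detected on all 4 arrays, whereas Bhlhe40 and Gria2 were undetected on both control arrays, and Epb41l3 was undetected on the dim array of each line, so the place of these 3 in the count rests on background. Outside the named genes, 525 probes without a gene name differed 2-fold with DOX in the same direction in both lines, 288 higher and 237 lower. They were 21.9% of 2393 detected probes without a name, against 21.3% of named probes.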

How the results depend on the processing

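No list median reversed its direction outside the middle of the random lists, and of the list medians under the alternatives 1203 stayed within the bootstrap interval of their members and 32 did not. Of the log2 ratios of named genes, 891 stayed within the spread between probes and 353 did not. With the authors' processed values 113 moved and 53 stayed, and without background correction 105 moved and 61 stayed. With an offset of 50, 85 moved and 81 stayed. All 166 stayed with a detection p of 0.05 and with no filter. The size of single-gene folds therefore depended on the background step and the scaling. No named ratio past 2-fold changed sign, and among smaller ones that of Hbp1 with MYC on did, from -0.07 to 0.04 with the mean of its probes. Against random lists not matched on expression, 7 percentiles crossed an edge of the middle 95% and 148 did not, and the study's targets with MYC on were among the 7, at 3.90. The cause of a shift was not tested unless named. Without background correction, the miR-17-92 effect was 9 higher and 6 lower with MYC on and 293 and 204 with MYC off, the difference 295 and 168, DOX in miR-17-92 cells 796 higher, the slope 0.804 and the SD ratio 0.827. With an offset of 50 the effect with MYC on was 31 and 24 and the difference 259 lower. An offset or an uncorrected background shrinks ratios of dim genes by construction. With the authors' processed values DOX gave 946 higher in control and 661 in miR-17-92 cells, the miR-17-92 effect 6 and 3 with MYC on and 336 and 166 with MYC off, and the difference 318 and 126. The medians were 1.16 for quiescence genes in control cells, and 1.17 and 0.86 for T-cell genes in control and miR-17-92 cells. Under these values the median of all genes was -0.13 and -0.06 in the DOX effects, against 0.06 and 0.09, and list medians should be read relative to it. Median scaling gave 52 lower with MYC on, and medians of -1.69 and -0.22 for DNA replication genes in control and miR-17-92 cells and 1.11 for T-cell genes in control cells. Detection on all 4 arrays, which tests fewer genes, gave 852 higher for DOX in miR-17-92 cells, 11 and 16 with MYC on, 248 lower with MYC off and 191 lower for the difference, with a slope of 0.7996 and an SD ratio of 0.823. A detection p of 0.05 gave 140 lower with MYC on, and no filter 143 and an SD ratio of 0.854. The interquartile range in place of the SD gave 0.787.

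In every setting the DNA replication gap between the lines lay between 1.31 and 1.51, and the study's targets with MYC off between -1.30 and -1.11. The search for miR-17-92 seed matches and its alternatives, 8-mer sites and no matching on length, were not run, since no transcript sequences were used here. A fit of the DOX effect paired by line, which would leave 1 residual degree of freedom, was not run. Signal over background limits the dim genes, which is why many extremes are given as bounds.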

Other observations

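The tests of explanations in this part were chosen after the results were seen. NF-kB genes were 2-fold higher in all 8 analysed cases in the control cells (median 1.98) and in 7 of 8 in the miR-17-92 cells (median 1.75), with Ltb, a lymphotoxin gene, at 4.04 and 4.43 and Tnfaip3, a brake on NF-kB, at 3.34 and 3.02. Antigen presentation genes of MHC class I were above 0 in all 9 cases in both lines (medians 1.08 and 0.90), with Tap2 at 1.89 and 1.77. Interferon genes had medians of 0.95 and 0.76 over 8 genes, inside the middle 95% of random lists (percentiles 96.8 and 96.3), with Gbp2 at least 20.7-fold and at least 7.68-fold higher and Bst2 at -1.66 and -1.87. With MYC off, 7 of these 8 genes were below 0 in the miR-17-92 cells (median -0.75, percentile 0.21). Their difference of the DOX effects had a median of -0.58 (percentile 1.49), and -0.45 was left after the scaling (percentile 2.64). Of 15 immediate early genes on the array 6 were analysed. By measured ratio 3 were 2-fold higher in control cells and 4 in miR-17-92 cells (medians 1.25 and 2.04), with Egr1 at 3.91 and 3.21. These 4 include Egr2, which was too near the floor for a fold. The p53 targets had medians of 1.24 and 0.62 over 13 genes (percentiles 99.8 and 96.9), with Trp53inp1 at 3.39 and 2.45 and Fas at 3.71 and 3.16. With MYC off they were below 0 in the miR-17-92 cells in 11 of 13 cases (median -0.48, percentile 0.52), while Cdkn1a was at least 3.85-fold higher there.

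Genes of the ATF4 response went apart within the list, with 4 of 15 2-fold higher and 7 lower in the control cells. Phgdh (-3.21) and Shmt2 (-3.67), of serine and glycine synthesis, were lower, and Ddit4 (3.24) and Vldlr (3.20) higher. With MYC off the list was above 0 in the miR-17-92 cells in 13 of 15 cases (median 0.69, percentile 100), with Psat1 at 1.61 and Asns at 1.54. Cholesterol synthesis genes had medians of -0.50 and -0.09 with DOX over 14 genes, with Lss at -2.02 and -1.04, and a difference of the DOX effects of 0.62 (percentile 99.9). Oxidative phosphorylation genes were below 0 in 16 of 18 cases in control cells (median -0.55) and in 13 of 18 in miR-17-92 cells (median -0.15). Of 20 ribosomal protein genes 6 were 2-fold lower in each line (medians -0.41 and -0.38), with Rplp0 at -2.82 and -2.41. Lysosome and autophagy genes had medians of 0.65 and 0.06 over 17 genes, and the second turned to -0.09 with the authors' processed values and -0.10 with detection on all 4 arrays. ER stress genes had medians of -0.14 and 0.14 over 13 genes, the second of which was -0.17 with the mean of a gene's probes, and Xbp1 stood at 2.42 and 1.21. Chromatin regulators had medians of 0.15 and 0.35 over 20 genes, and the first was -0.19 with the authors' processed values. Dnmt3b was lower, at -3.11 and -1.98, and Kdm5b higher, at 2.71 and 1.78. The 10 housekeeping genes had medians of -0.06 and 0.09, the second of which was -0.21 with median scaling and -0.14 with the authors' processed values, and Pgk1 and Gapdh, also glycolysis genes, were 1.65 and 0.91 higher in the miR-17-92 cells with MYC off. Of the remaining markers of other cells, Prf1 stood at 1.38 and 0.44 with DOX and Pecam1 at 1.91 and 1.41.

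The study's named targets were lower in the miR-17-92 cells with MYC off by a median of log2 -1.30, and genes higher with DOX were lower there in general. Random lists matched on the mean DOX effect of the lines had a median of -0.43, those matched on the control cells -0.66 and those matched on the miR-17-92 cells -0.16. The MYC-off ratio shares an array with each DOX effect, which shifts the last 2 in opposite directions. The targets lay at percentiles 0.455, 2.03 and 0.14 of these, and -0.70 of their difference of the DOX effects was left after scaling by the slope over all genes (percentile 0.16). All 4 percentiles lie below the middle 95% of random lists, against the trend as the whole cause, but the study may have chosen the genes on these arrays, so the pattern cannot be told apart from the trend by these tests. A misreading probe is argued against, as 14 of 14 detected probes were lower, although Sin3b has only 1. Repression that reaches the reported targets of the cluster in general was not seen beyond this trend, since 21 such genes had a median of -0.30 at percentile 16.3 of lists matched on the mean DOX effect, 28.6 on the control and 9.21 on the miR-17-92 cells. Their difference of the DOX effects had a median of -0.01 (percentile 47.3), with 10 above 0 and 11 below, and 0.12 was left after scaling (percentile 81.3). With members on both sides this decides nothing, and it stays open as a hypothesis.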
